A study of Mus musculus with 4 samples.

How the data were processed

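Single-nucleus RNA was measured in 4 libraries from snap-frozen brain hemispheres of C57BL/6 mice at postnatal day 14. Per the labels, 2 libraries carried Slc17a6-Cre with unaltered Ago2 (WT) and 2 carried Slc17a6-Cre with both Ago2 alleles floxed (Ago2 cKO). Nuclei were captured with 10x Genomics 3′ v3 chemistry and sequenced on a NovaSeq. Each library was deposited as a matrix of integer UMI counts per gene and nucleus barcode. The submitters' processing notes name Cell Ranger 4.0.0, Seurat 3.2.3 and the GRCm38 build, and the matrix headers name Cell Ranger 4.0.0 as well. The intron setting and the annotation release used for counting were not given in the sources used here. Whether the 2 libraries of a group came from separate animals is not stated, so each p measures the spread between libraries. Handling, time of day and preparation batch per library were not given in the sources used here and cannot be told apart from genotype.

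The files held 32286 features and 17802 barcodes, and the lowest total per barcode was 500 UMIs. Barcodes with at least 500 UMIs and under 5% mitochondrial UMIs were kept. The UMI minimum removed 0 barcodes. The mitochondrial maximum removed 17.8% and 8.78% of barcodes from WT replicates 1 and 2, and 5.64% and 6.14% from cKO replicates 1 and 2. Doublets were scored within each library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 1 to 2 nuclei per library, so the highest scores were marked up to a rate of 0.8% per 1000 barcodes. This removed 114 and 337 nuclei from the WT libraries and 95 and 93 from the cKO libraries. In all, 15437 nuclei were kept.

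Counts were scaled to 10000 UMIs per nucleus and log-transformed, and 2000 variable genes, chosen per library, entered a principal component analysis with 30 components. Ago2, sex-linked and mitochondrially encoded genes were left out of this step. A graph of 15 nearest neighbours was partitioned with the Leiden algorithm (igraph 0.11.9) at resolution 1, giving 28 clusters. Clusters were named from marker lists for neurons, glia, vessels, meninges, ependyma, choroid plexus and blood. A marker counted as detected in a cluster when at least 10% of its nuclei had a UMI and its level was at least 2-fold above the other clusters. A class name needed 3 detected markers and a mean log2 fold of 0.5. Clusters with median depth far below their library, or led by macrophage genes, were left unnamed. Classes are thus astrocyte-like, oligodendrocyte-like and so on, and are called by the plain name from here on. Unnamed clusters held 29.3% and 23.9% of the nuclei in WT replicates 1 and 2, and 29.6% and 27.0% in cKO replicates 1 and 2. Striatal spiny neurons counted as GABAergic and committed precursors as oligodendrocytes. Cluster 10, 959 of the 2223 GABAergic nuclei, scored first for immature neuron markers (1.3) and second for GABAergic markers (1.17). The vascular class is the sum of endothelial and mural nuclei.

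UMI counts were summed per library and class wherever each library had at least 20 nuclei of the class. The sums were compared between genotypes with the edgeR 4.0.16 quasi-likelihood test (filterByExpr, TMM scaling, two-sided) in R 4.3.3. Benjamini-Hochberg adjustment was applied within each class at a threshold of 0.05. Log2 changes are cKO relative to WT, and their standard errors (SE) come from the fit. Levels are CPM, the counts scaled by the class sum, given as mean ± SD over the 2 libraries of a group. With 2 libraries against 2, the smallest two-sided exact permutation p is 0.333, and chance alone separates the groups for 33.3% of genes. Across classes the groups were separated for 31.7% to 39.0% of the genes tested. The difference in genotype effect between glutamatergic nuclei and GABAergic nuclei or astrocytes was tested as an interaction, with the library as a block. Shares of nuclei were compared with the edgeR quasi-likelihood test on nuclei per class, with all nuclei of the library as the total. For a gene or class with 1 to 3 counts in a group, the ratio is given with its exact 95% interval. For 0 counts, a bound against 3 counts over the group is given. Intervals cover counting error only.

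Gene lists for 31 pairs of list and class were tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 tested members), adjusted over the pairs. They covered vascular guidance ligands, glutamate receptors and postsynaptic density, presynaptic release machinery, immediate early genes, axon guidance receptors, the miRNA pathway, hypoxia response, blood-brain barrier, angiogenic endothelial genes, mural genes, basement membrane, astrocyte endfoot and maturation, reactive astrocytes, homeostatic and activated microglia, myelin and OPC genes. Sex-linked, mitochondrially encoded, stress, thalamic, hippocampal granule, cerebellar granule, upper-layer and deep-layer lists were described without a test. Genes with an 8mer site for 1 of 12 miRNA families in the 3′ UTR were tested in the same way against genes with a UTR and no site. The families were 9 abundant in neurons and 3 for comparison. UTRs came from GENCODE annotation of GRCm38, and 32158 of the 32286 feature identifiers matched it.

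Genes were named by rule. In each class these were Ago2, then up to 12 genes that rose and 12 that fell past the threshold with the smallest p and separated groups, and up to 4 members of each list. Where fewer than 5 genes passed, the 5 with the smallest p were added as not passing. Predicted genes were named only among the 3 smallest p. Some genes that the rule names are not reported here, and they remain in the counts. The samples per group, tests, gene lists, markers, naming rule and most alternatives were set before the data were examined. The following were set after the data were seen: the mitochondrial maximum, the doublet rate, the thresholds for naming clusters, 8 added classes, the use of the longest UTR, the tolerance for matching UTR length, 2 hypothesis lists, and 3 kinds of alternative. These alternatives are nuclei under 1% mitochondrial, a crossed replicate block, and leaving out 1 cluster of a class. The other alternatives were another scaling, the DESeq2 1.42.0 Wald test, no low-count filter, the replicate number as a block, each library left out, doublets kept, at least 1000 UMIs, and Leiden resolutions 0.5 and 2. For lists they were an estimated correlation and fry, and for sites a wider site definition and a background matched on UTR length. A feature named CRE had 0 UMIs in all 4 libraries, a limit of 0.0464 CPM, and was left out of the sums.

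The tests were tested on simulated data, with the depth and spread of each class for genes and of glutamatergic nuclei for lists and sites. Of 100 genes changed 2-fold, 45 were called in glutamatergic nuclei, 46 in GABAergic nuclei, 44 in astrocytes, 37 in oligodendrocytes, 53 in OPC, 39 over all nuclei and 19 each in microglia, endothelial and vascular nuclei. Of 100 genes changed 4-fold, between 75 and 90 were called. With no gene changed, 2 genes were called in glutamatergic nuclei, 3 in vascular nuclei and 0 in each other class simulated. Beside 200 changed genes, the unchanged genes called ranged from 1 in endothelial nuclei to 12 over all nuclei. The interaction against GABAergic nuclei called 19 of 94 genes at 2-fold and 71 of 94 at 4-fold, and against astrocytes 7 of 76 and 55 of 75. Of 10 lists raised 1.5-fold, 10 were called with the preset correlation and 8 with an estimated one. Sites of let-7 raised 1.1-fold in the nuclear counts gave a camera adjusted p of 1.51e-05. Genes were simulated as independent, so the recovery of lists and sites may be overstated where genes are correlated. A class with a doubled share was called in 7 of 20 simulated sets and a class raised 4-fold in 20 of 20, with 36 unchanged classes called beside the latter.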

Results

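Gene expression was measured in single nuclei from brain hemispheres of mice at postnatal day 14, in 2 WT libraries and 2 libraries labelled Ago2 cKO. Slc17a6-Cre drives recombination in neurons that express the vesicular glutamate transporter VGLUT2. Ago2 is an Argonaute protein that binds miRNAs and represses their target mRNAs. WT replicates 1 and 2 held 13107920 and 29317266 UMIs in 4066 and 6752 barcodes. The cKO replicates 1 and 2 held 10845009 and 11439733 UMIs in 3512 and 3472 barcodes. After filtering, 3230 and 5822 WT nuclei and 3219 and 3166 cKO nuclei remained, with medians of 2408, 3093, 2314 and 2376.5 UMIs. The design text speaks of cortical cells and the protocol of hemispheres, and cerebellar granule neurons made up 16.0% to 22.6% of the nuclei of a library.

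The comparison in glutamatergic nuclei asks what loss of Ago2 does within excitatory neurons. Ago2 itself was not lower in libraries labelled cKO: its level was 77.7 ± 6.68 CPM in WT and 103 ± 3.07 in cKO (SD, n = 2 libraries each). The log2 change was 0.40 (SE 0.16), with both cKO libraries above both WT libraries. The edgeR p was 0.0257 unadjusted and 0.926 adjusted over all genes, and the DESeq2 unadjusted p was 0.0803. The gene lies on chromosome 15 of GRCm38 from 73095844 to 73184935 and its longest transcript has 19 exons. The labels do not name the deleted exons, and 3′ tags outside them do not check the deletion. Across 13 separate classes, Ago2 was higher in cKO in 8 and past the threshold in 0 by edgeR. At postnatal day 14 the glutamatergic class carried little of the driver gene. Slc17a6 averaged 15.5 and 5.24 CPM in the clusters of this class, 1 and 7. It averaged 71.9 in the unnamed cluster 15 and 125 in the unnamed cluster 18. Expression of the driver gene before this age was not measured, so these levels do not show which nuclei lost Ago2.

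**Figure D1:**
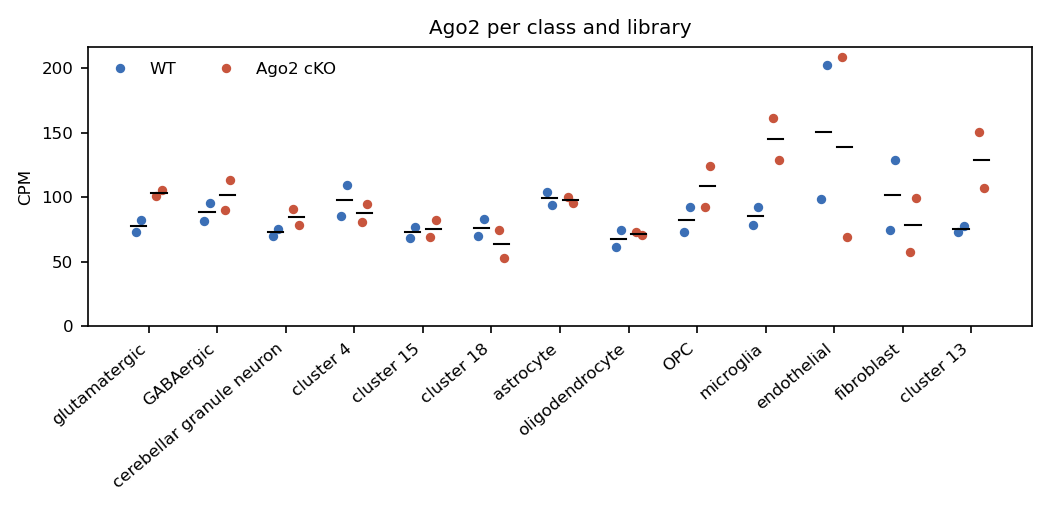
Ago2 level in CPM for each class, with 1 dot per library and a line at the mean of the 2 libraries of each genotype. In glutamatergic nuclei the WT libraries sit at 72.9 and 82.4 and the cKO libraries at 101 and 106.

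In glutamatergic nuclei, 2 of 11065 genes fell and 0 rose. The simulation with no gene changed also called 2 genes in this class. Mbp, which encodes myelin basic protein, went from 263 ± 1.43 to 127 ± 1.49 CPM (log2 change -1.06, SE 0.14, adjusted p 0.0403). The long non-coding RNA Gm20752 went from 47.0 ± 2.04 to 9.02 ± 2.18 (log2 change -2.38, SE 0.27, adjusted p 0.0135). Mbp was also lower in 12 of 13 separate classes, all except oligodendrocytes. The other genes with the smallest p did not pass. Kcnmb2, a potassium channel subunit, had a log2 change of 1.02 (adjusted p 0.279), Fth1, the ferritin heavy chain, -1.29 (0.312), and Dnah9, an axonemal dynein, 0.96 (0.312). By edgeR 572 genes had an unadjusted p under 0.05, and DESeq2 called 2. Leaving out WT replicate 1, WT replicate 2, cKO replicate 1 or cKO replicate 2 gave 24, 16, 38 or 0 genes.

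None of the 7 lists tested in glutamatergic nuclei passed, with camera adjusted p from 0.776 to 0.931 and 0 members past the threshold over all genes. Of 27 presynaptic release genes, 11 had positive and 16 negative changes, and 1 passed adjusted over the list alone. That gene was Syt4, a vesicle synaptotagmin, at 30.8 ± 3.44 in WT and 54.5 ± 0.93 in cKO (log2 change 0.81, SE 0.20). Syp had a change of 0.57, Nrxn2 of 0.35 and Stx1a of -0.29. The median of this list was -0.08, while its mean was 0.01 and the test pointed up. Among 27 axon guidance receptors, 14 were positive and 0 passed adjusted over the list alone. Robo3 had a change of -0.95, Sema6a of 0.50, Plxnc1 of 0.59 and Robo1 of -0.40. Vascular guidance ligands, the signals from neurons to vessels, had 13 positive and 10 negative members and 0 passed adjusted over the list alone. Slit2 had a change of -0.60, Sema3c of -0.79, Fgf1 of 0.35 and Reln of 0.36, and the median of the list was 0.03 while the test pointed down. Glutamate receptors and postsynaptic density genes split 16 to 16, immediate early genes 6 to 6 and hypoxia response genes 7 to 7, each with 0 past adjusted over the list alone. Grik1 had a change of 0.33, Jund of -0.85 and Pfkfb4 of 0.35. Of 15 miRNA pathway genes 11 were positive, with 0 past adjusted over the list alone, Tarbp2 at -0.59 and Ago1 at -0.25.

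Targets of neuronal miRNAs were compared because Ago2 represses them, and their levels in nuclei did not differ detectably as sets. The counts came from nuclei alone, and the deletion of Ago2 could not be checked from them. The comparison thus does not show whether targets stay repressed without Ago2. None of 12 families passed the camera test, and the smallest adjusted p was 0.922. Genes with a miR-124-3p site had a median log2 change of 0.01 over 374 genes, against 9475 genes without one, and those with a miR-128-3p site 0.02 over 647 genes. Genes with a let-7 site had a median of -0.01 over 381 genes. Of the 9 neuronal families, 7 pointed up, and so did 2 of the 3 comparison families. The smallest unadjusted camera p, 0.268, was that of the comparison family miR-122-5p. The number of neuronal families pointing up was 1 without cKO replicate 2, 3 without WT replicate 1, 8 without cKO replicate 1 and 9 without WT replicate 2. The number of families past the threshold was 0 in each of these.

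The comparison in GABAergic nuclei asks whether inhibitory neurons change as well. None of 10788 genes passed by edgeR, 474 had an unadjusted p under 0.05, and DESeq2 called 1. The genes with the smallest p were all lower in cKO without passing. Mbp had a log2 change of -1.33 (SE 0.22), Fth1 of -1.39, the ribosomal gene Rplp1 of -1.46, the pericyte gene Rgs5 of -2.54, and Faah, which breaks down endocannabinoids, of -1.25, each with an adjusted p of 0.716. Ago2 had a change of 0.19 (SE 0.17, adjusted p 0.999). Leaving out WT replicate 1, WT replicate 2, cKO replicate 1 or cKO replicate 2 gave 6, 16, 44 or 9 genes.

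The 7 lists in GABAergic nuclei did not pass, with camera adjusted p from 0.0999 to 0.931. Immediate early genes, induced by neuronal activity, had 1 positive and 11 negative members and the adjusted p of 0.0999. Btg2 had a change of -1.42, Jun of -0.97, Jund of -0.96 and Junb of -0.48. Of 32 glutamate receptor and postsynaptic genes, 17 were positive and 1 passed adjusted over the list alone. That gene was Grin3a, an NMDA receptor subunit, at 267 ± 22.1 in WT and 161 ± 34.1 in cKO (log2 change -0.73, SE 0.17). Grik1 had a change of -0.66 and Grin2a of -0.27, and the median of this list was 0.006 while the mean was -0.014. Vascular guidance ligands included Vegfb at -1.17, Reln at -0.53, Angpt1 at 0.46 and Slit3 at 0.33, with 0 of 24 past adjusted over the list alone. Axon guidance receptors had 15 positive and 13 negative members, with Robo3 at -1.61, Plxnb1 at 1.05, Sema6d at -0.26 and Plxna1 at -0.72, and a mean of -0.02 against a median of 0.05. Hypoxia response genes had 5 positive and 8 negative members, with Slc2a1 at -1.09 and Pgk1 at -0.72. Presynaptic genes had 11 positive and 17 negative members, with Cplx1 at -0.40, and miRNA pathway genes had 12 positive and 4 negative members, with Cnot1 at 0.29. In these 4 lists 0 passed adjusted over the list alone.

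The genotype effect differed between glutamatergic and GABAergic nuclei for 12 genes. The glutamate receptor subunits Grin3a and Grik1 had changes of 0.33 and 0.33 in glutamatergic nuclei against -0.73 and -0.66 in GABAergic nuclei, differences of 1.07 (SE 0.16, adjusted p 0.00079) and 0.98 (SE 0.16, adjusted p 0.00237). For Kcnmb2 the difference was 1.36 (SE 0.21, adjusted p 0.00079). The interneuron transcription factor Sox6 and the glycoprotein Reln had differences of 1.27 and 0.87. The GABAergic cluster 11, led by Sst, Npy, Lhx6 and Kcnmb2, was 14.9% and 18.6% of the GABAergic nuclei in the WT libraries and 12.5% and 8.39% in the cKO libraries. Without that cluster 0 of the genes passed, and without WT replicate 2 also 0. Without cKO replicate 2 or WT replicate 1 the count was 35 or 22.

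Astrocytes contact synapses and vessels, and in them 8 of 8923 genes rose and 3 fell. Fkbp5, a co-chaperone of the glucocorticoid receptor on chromosome 17, rose from 12.8 ± 2.01 to 127 ± 9.03 CPM (log2 change 3.28, SE 0.27, adjusted p 0.000498). The transcription factor Zfhx3 rose by 1.40 (SE 0.19), the AMPA receptor partner Shisa6 by 1.40 (SE 0.20), the potassium channel partner Kcnip1 by 1.82 (SE 0.28), the sarcoglycan Sgcd by 1.05 (SE 0.16) and Tmcc3 by 0.92 (SE 0.14). Unc13c, known for priming synaptic vesicles, fell from 679 ± 37.9 to 212 ± 49.8 (log2 change -1.68, SE 0.17, adjusted p 0.00283). Predicted and uncharacterised genes were among the other calls. All 11 genes stayed past the threshold when each library in turn was left out, while the total became 26, 110, 49 and 270 without WT replicate 1, WT replicate 2, cKO replicate 1 and cKO replicate 2. Zfhx3 is also on the thalamic list, which had 7 of 8 members positive in astrocytes. At Leiden resolution 2 astrocytes lay in its clusters 3, 17 and 23. Cluster 3 held 185 and 247 WT and 111 and 167 cKO nuclei. Cluster 17 held 45 and 91 WT and 51 and 54 cKO nuclei, and cluster 23 held 112 and 152 WT and 114 and 135 cKO nuclei. A changed mix of these parts was not separated from changes within them.

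**Figure D2:**
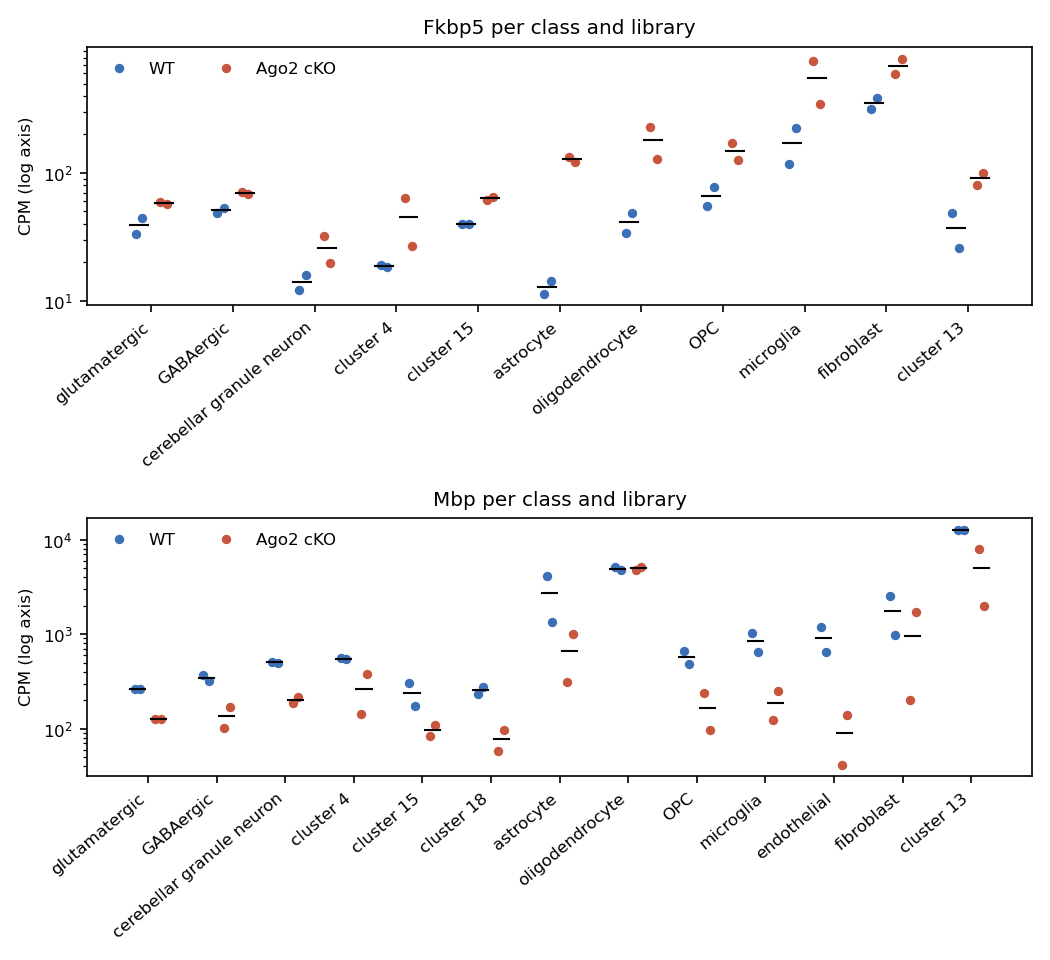
Fkbp5 and Mbp levels in CPM on a log axis for each class, with 1 dot per library and a line at the mean of the 2 libraries of each genotype. Fkbp5 was 11.3 and 14.2 in WT astrocytes and 134 and 121 in cKO astrocytes, and Mbp had a log2 change of 0.003 in oligodendrocytes.

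The effect on Fkbp5 and Unc13c differed between glutamatergic nuclei and astrocytes. Fkbp5 had a change of 0.55 in glutamatergic nuclei, and the difference of -2.75 (SE 0.32) had an adjusted p of 5.47e-05. Unc13c had a change of 0.38 in glutamatergic nuclei, and the difference of 2.05 (SE 0.22) had an adjusted p of 4.47e-05. Both passed with each library left out, while the count of genes was 3, 6, 8 and 55 without WT replicate 1, WT replicate 2, cKO replicate 1 and cKO replicate 2.

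None of the astrocyte lists passed. In the list of endfoot and maturation genes 8 of 18 were positive and 1 passed adjusted over the list alone. It was Aqp4, the water channel of astrocyte endfeet at vessels, at 283 ± 5.87 in WT and 162 ± 18 in cKO (log2 change -0.81, SE 0.16, adjusted p 0.126 over all genes). Slc1a2 had a change of -0.17 and Hepacam of 0.17. Of 5 reactive astrocyte genes tested, 4 were positive, with Stat3 at 0.42, Cp at 0.68, Osmr at 0.20 and Gfap at 0.07 (camera adjusted p 0.355). Hypoxia response genes had 3 positive and 10 negative members (camera adjusted p 0.138), with Pfkfb4 at -0.82, Mxi1 at -0.42, Bnip3l at -0.63 and P4ha1 at -0.37. Vascular guidance ligands had 13 positive and 9 negative members, with Ntn1 at 0.78, Spock2 at -0.63, Angpt1 at 0.70 and Slit3 at 0.41 (camera adjusted p 0.801). Basement membrane genes had 6 positive and 7 negative members, with Itga6 at -0.34, and miRNA pathway genes had 12 positive and 3 negative members. In these 5 lists 0 passed adjusted over the list alone.

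In oligodendrocytes 5 of 6742 genes rose and 1 fell. Hif3a, a member of the hypoxia-inducible factor family on chromosome 7, had 3 UMIs in WT and 72 in cKO, a ratio of 59.5 (95% interval 19.6 to 295). Fkbp5 rose from 41.1 ± 10.0 to 179 ± 71.2 CPM (log2 change 2.05, SE 0.29, adjusted p 0.00484). Adipor2, an adiponectin receptor, rose by 1.94 (SE 0.27), Dlc1 by 1.41 (SE 0.20) and Scrg1 by 1.45 (SE 0.22). The laminin chain Lama2 fell from 164 ± 23.8 to 44.2 ± 16.6 (log2 change -1.85, SE 0.28, adjusted p 0.00869). The myelin list rose as a group, with 12 of 15 members positive and a camera adjusted p of 0.00707, and the adjusted p was 0.915 with an estimated correlation. The class joins committed precursors with mature cells, cluster 9, which is led by myelin genes and was 47.7% and 51.0% of the class in the WT libraries and 58.4% and 49.7% in the cKO libraries. Mal, Mog and Cldn11, all parts of the myelin sheath, had changes of 0.68, 0.61 and 0.57 and passed adjusted over the list alone, but 0 members passed over all genes. Mbp had a change of 0.003 (SE 0.17). The count of genes was 7, 18, 23 and 129 without WT replicate 1, WT replicate 2, cKO replicate 1 and cKO replicate 2. The list myelin in oligodendrocyte nuclei had an adjusted p of 0.0532 without WT replicate 2 and 0.185 without cKO replicate 1.

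In oligodendrocyte precursors (OPC) 7 of 6177 genes rose and 25 fell. Those that rose included Inpp4b, a phosphoinositide phosphatase, from 388 ± 78.4 to 836 ± 125 CPM (log2 change 1.09, SE 0.17, adjusted p 0.000625), and Kcnip1, by 0.87 (SE 0.17). Fkbp5 rose by 1.09 (SE 0.26), Hif3a by 2.69 (SE 0.61), the secreted protease Htra1 by 1.58 (SE 0.35), Ptgfrn by 1.62 (SE 0.36) and Disc1 by 1.11 (SE 0.26). Mbp fell from 570 ± 123 to 166 ± 99.2 (log2 change -1.79, SE 0.24, adjusted p 8.81e-05), and the adhesion gene Ninj2 and Fth1 had changes of -1.77 and -1.88. Of 10 mitochondrially encoded genes 6 fell, such as mt-Co1 with a change of -1.50 and mt-Co3 with -1.47, and the list had a negative median in each of the other classes too. Without WT replicate 1 these were -0.57 and -0.35 and neither passed. Top2a, a topoisomerase of replicating DNA, had a change of -1.91 (SE 0.37), the kinetochore gene Knl1 of -2.61 (SE 0.53) and the non-coding RNA Lockd of -2.65 (SE 0.53). With a library left out these ranged from -2.618 to -1.308, -4.216 to -1.965 and -3.09 to -2.326. The mitotic kinesin Kif4 had 54 UMIs in WT and 3 in cKO, a ratio of 10.2 in favour of WT (95% interval 3.32 to 51.2). Chosen after their values were seen, Mki67 had 44 against 3 UMIs (ratio 8.34, 2.67 to 42) and Cdca8 39 against 1 (ratio 22.2, 3.75 to 898). Cluster 26, 39 OPC nuclei led by Top2a, held 8 and 27 nuclei of the WT libraries and 2 and 2 of the cKO libraries, and without it 7 genes passed. DESeq2 called 1 gene, and 3 passed with doublets kept. OPC genes did not pass as a list, with 7 of 13 positive, 0 past adjusted over the list alone, and changes of 0.31 for Cspg4, 0.31 for Sox10, 0.18 for Pdgfra and -0.17 for Cspg5. Leaving out single libraries gave 24 to 42 genes, of which 15, 15, 19 and 20 of the 32 remained without WT replicate 1, WT replicate 2, cKO replicate 1 and cKO replicate 2.

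In microglia 0 of 3475 genes passed by edgeR, 197 had an unadjusted p under 0.05, and DESeq2 called 0. The genes with the smallest p were Mbp (log2 change -2.13, SE 0.38), Tmem44 (-2.82), Megf11 (1.75), Reln (1.76) and Hs3st5 (1.49), each with an adjusted p of 0.245. Of 11 homeostatic microglia genes, 9 were negative (camera adjusted p 0.138) and 0 passed adjusted over the list alone. Fcrls had a change of -0.92 (SE 0.31), Selplg of -0.43, Gpr34 of -0.34 and the growth factor receptor Csf1r of -0.28. Only 4 activated microglia genes were measured, too few for the test, with Tyrobp at -0.25, Trem2 at -0.21, Ctsb at 0.12 and Apoe at -0.11. Leaving out cKO replicate 1 gave 49 genes and leaving out WT replicate 2 gave 3.

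The vascular comparisons ask whether loss of Ago2 in neurons reaches the vessels. Among 2416 genes in endothelial nuclei 2 rose and 4 fell. Igfbp3, which binds insulin-like growth factors and lies on chromosome 11, had 0 UMIs in WT and 46 in cKO, at least 20.2-fold higher against a floor of 3 counts over the group, with an exact 95% lower limit of 15.7. The leukotriene receptor Cysltr1 rose from 88.8 ± 13.8 to 513 ± 106 CPM (log2 change 2.57, SE 0.40, adjusted p 0.0272). Mbp fell by 3.13 on the log2 scale, the glutamate receptor Grm3 by 2.62 and Atp13a5 by 3.45. Atp13a5 is on the list of mural markers, and endothelial nuclei numbered 40, 51, 25 and 43 in WT replicates 1 and 2 and cKO replicates 1 and 2. Blood-brain barrier genes had 12 of 20 positive, among them the glucose transporter Slc2a1 at 304 ± 104 in WT and 758 ± 77.8 in cKO (log2 change 1.26, SE 0.35, adjusted p 0.306), with Abcc4 at 0.71, Slco1a4 at 0.54 and Tjp1 at 0.54. Angiogenic genes had 6 positive and 5 negative members, with Pecam1 at 0.69, Tek at 0.52, Nrp1 at -0.40 and the VEGF receptor Kdr at -0.29. Basement membrane genes had 2 positive and 10 negative members (camera adjusted p 0.0949), with Lamc1 at -0.87, Nid1 at -1.30, Itgb1 at -0.85 and Sparc at -0.60. In these 3 lists 0 passed adjusted over the list alone. Without WT replicate 2, and at Leiden resolution 2, 0 genes passed, and without WT replicate 1, cKO replicate 1 and cKO replicate 2 the counts were 25, 26 and 61.

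In the vascular class, endothelial and mural nuclei together, 1 of 3811 genes rose and 0 fell, with 279 at an unadjusted p under 0.05 and 0 called by DESeq2. That gene was Igfbp3, with 1 UMI in WT and 48 in cKO, a ratio of 69.6 (95% interval 11.9 to 2800). The simulation with no gene changed called 3 genes in this class. Mural genes, which mark pericytes and smooth muscle, fell as a group. All 13 members were negative with a median of -1.17 (camera adjusted p 3.5e-11), and the adjusted p was 0.915 with an estimated correlation. Vtn had a change of -1.57 (SE 0.32), Pdgfrb, the pericyte receptor for platelet-derived growth factor, of -1.12 (SE 0.34), Abcc9 of -1.66 and Atp13a5 of -1.40, and 6 members passed adjusted over the list alone. Mural nuclei were 26 of 66 and 23 of 74 nuclei of this class in the WT libraries. In the cKO libraries they were 5 of 30 and 24 of 67, too few to test alone. The fall of the list was not separated from the smaller mural part in cKO replicate 1. Basement membrane genes also fell as a group, with 14 of 17 negative and a camera adjusted p of 0.00705, 0.915 with an estimated correlation and 0.315 without cKO replicate 1. Lamc1 had a change of -1.10, Nid2 of -2.09 and Itgb1 of -0.77 against 0.68 for Fn1, and 0 passed adjusted over the list alone. Blood-brain barrier genes had 15 of 22 positive (camera adjusted p 0.0733), with Slc2a1 at 1.41 (SE 0.38), Slco1a4 at 0.76, Abcc4 at 0.92 and Tjp1 at 0.71, and 0 passed adjusted over the list alone. Slc2a1 is also on the list of hypoxia response genes, where it alone of 6 passed adjusted over the list alone, with Egln1 at -1.17, Bnip3l at -1.29 and Mxi1 at -0.43. Angiogenic genes had 7 positive and 9 negative members, Tek at 0.70, Pecam1 at 0.94, Mcam at -0.78 and Nrp2 at 0.78, and their median of -0.09 was negative while the test pointed up. Cysltr1 had a change of 2.21, Vegfc, a lymphatic growth factor, of 3.37 and Gm5127 of 3.03 without passing, and Vcam1, with 0 UMIs in WT and 25 in cKO, did not pass either (adjusted p 0.257). It was at least 12.1-fold higher against the floor of 3 counts over the group, with an exact 95% lower limit of 9.12. Igfbp3 did not pass without WT replicate 2, where the count was 0 and WT replicate 1 had 0 UMIs of it, and the counts were 11, 24 and 96 without WT replicate 1, cKO replicate 1 and cKO replicate 2.

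Over all nuclei 0 of 16975 genes passed by edgeR, 1003 had an unadjusted p under 0.05, and DESeq2 called 38. Dnah12, a dynein of motile cilia, had 3.54 ± 0.05 CPM in WT and 18.3 ± 2.77 in cKO (log2 change 2.36, SE 0.23, adjusted p 0.0761). Fkbp5 had 44.0 ± 3.26 in WT and 94.7 ± 0.78 in cKO (adjusted p 0.11). Gm20752 had a change of -2.05, Unc5cl of 3.41 and Zfp474 of 3.80, and none of these passed. Dnah12 and Unc5cl are among the leading genes of the ependymal cluster, which held 3 WT and 22 cKO nuclei. Ago2 had a change of 0.18 (SE 0.13). Without cKO replicate 1 the count was 89 and without cKO replicate 2 it was 364.

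The makeup of the tissue was compared through the share of nuclei per class. Ependymal nuclei, the ciliated lining of the ventricles, were 0.031% and 0.034% of nuclei in the WT libraries and 0.311% and 0.379% in the cKO libraries (log2 ratio 3.26, SE 0.41, adjusted p 0.0105). These are 3 WT and 22 cKO nuclei, a ratio of 10.4 (95% interval 3.12 to 54.3). The mitochondrial maximum, set after the data were seen, removed most barcodes with at least 3 ependymal markers. It removed 44 of 50 in WT and 49 of 70 in cKO. With them put back the log2 ratio of such barcodes was 0.955 (SE 0.65), against 2.32 for those kept. Exact 95% intervals reached from 0.001% to 0.172% and 0.004% to 0.124% in WT replicates 1 and 2, and from 0.149% to 0.571% and 0.196% to 0.661% in cKO replicates 1 and 2, and those of WT replicate 1 and cKO replicate 1 overlap. Cluster 15, an unnamed and mixed neuronal cluster with Slc17a6 in 28.2% and Gad2 in 34.7% of its nuclei, was 7.99% and 8.59% in WT and 12.4% and 13.4% in cKO (log2 ratio 0.64, SE 0.16, adjusted p 0.0931). Oligodendrocytes were 6.10% and 6.20% in WT and 3.88% and 4.77% in cKO (log2 ratio -0.51, SE 0.18, adjusted p 0.235). Glutamatergic nuclei (log2 ratio -0.13), GABAergic nuclei (0.22), astrocytes (0.06), microglia (0.11), OPC (-0.11), endothelial nuclei (0.04) and mural nuclei (-0.32) did not pass either, with adjusted p from 0.772 to 0.962. The exact permutation p of the ependymal share was 0.33, the smallest that 2 against 2 allows. The ependymal call was lost without WT replicate 1 (log2 ratio 3.22, adjusted p 0.18) and without WT replicate 2 (3.32, 0.257), with little change in the ratio, and in nuclei under 1% mitochondrial, where the log2 ratio was 0.35.

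**Figure D3:**
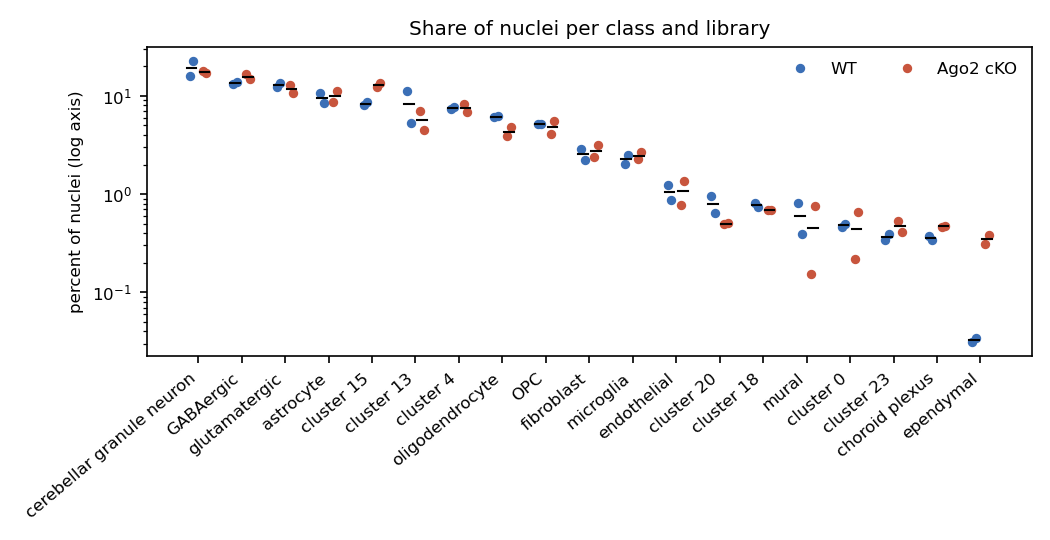
Share of all nuclei kept, in percent on a log axis, for each class, with 1 dot per library and a line at the mean of the 2 libraries of each genotype. Ependymal nuclei sit at 0.031% and 0.034% in WT and at 0.311% and 0.379% in cKO.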

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

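The test of free RNA for Fkbp5 was chosen only after the result was seen, and the glucocorticoid and fasting lists were written after Fkbp5 was seen and before their own tests.

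The genotype effect differed between glutamatergic and GABAergic nuclei by a test of the difference for 12 genes, given as the log2 change in glutamatergic less that in GABAergic nuclei. The glutamate receptor subunits Grin3a and Grik1 differed by 1.066 and 0.978 and the potassium channel subunit Kcnmb2 by 1.363. The hyaluronan-binding gene Cemip differed by 1.07 and Faah, which breaks down endocannabinoids, by 1.244. The transcription factors Sox6, Zfp536 and Npas3 differed by 1.274, 0.804 and 0.796 and the secreted glycoprotein Reln by 0.869. Tmc1, a channel subunit of hair cells, differed by 4.115, and the non-coding RNAs Sox1ot and 6330411D24Rik by 2.421 and 1.69. Tmc1 was not tested within either class alone, and the other 11 genes did not pass in either. Of the 12 genes, 0 passed without the GABAergic cluster 11 and 0 without WT replicate 2.

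The effect also differed between glutamatergic nuclei and astrocytes for 2 genes. Unc13c, known for priming synaptic vesicles, differed by 2.048. Fkbp5, a co-chaperone of the glucocorticoid receptor, differed by -2.752, with log2 changes of 0.55 in glutamatergic nuclei and 3.28 in astrocytes.

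Fkbp5 was higher in both cKO libraries than in both WT libraries in 11 of the 11 separate classes in which it was tested, and free RNA spread evenly over the nuclei is argued against, because the highest difference in level over classes, 382 CPM in microglia, was 7.15 times the median difference. A glucocorticoid response in the cKO animals is a candidate explanation: other listed response genes, without Fkbp5 and Hif3a, were higher as a set in astrocytes (camera p 0.000169), oligodendrocytes (0.00122), OPC (1.38e-09), endothelial nuclei (0.000653), vascular nuclei (4.06e-05), fibroblasts (0.00372) and granule neurons (0.0474), with p from 0.0574 to 0.327 with an estimated correlation. The camera p are not adjusted over the classes, and the vascular nuclei include the endothelial nuclei. In OPC 1 of the 7 listed members tested had itself passed over all genes. The set was not detectably higher in microglia (4 of 8 positive, p 0.92), glutamatergic nuclei (6 of 12, p 0.421), GABAergic nuclei (5 of 13, p 0.743), cluster 4 (2 of 7, p 0.236), cluster 13 (9 of 12, p 0.237) or cluster 15 (7 of 14, p 0.278). A fasting response cannot be told apart, since 7 of its 8 listed genes were positive in astrocytes with a camera p of 0.144, and the bound set beforehand was wrong because a p that misses the threshold excludes nothing. Handling and time of collection, which can raise glucocorticoids, and an effect of genotype stay open.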

How the results depend on the processing

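The alternatives with nuclei under 1% mitochondrial, a crossed replicate block and 1 cluster left out were added after seeing the data. Of 1185 alternative values for 94 results, 808 kept their direction and side of the threshold or stayed within 1.5 times the count, 235 kept the direction without passing, 142 counts moved by more, and 0 reversed. Of these results 71 were single calls past the threshold and 23 were mainly counts, which have no direction, so few could reverse. Shares that were not called did reverse in some settings. The OPC log2 ratio was -0.107 in the main setting and 0.053 as a ratio to glutamatergic nuclei. Named calls passed in 69 of 70 with other size factors, 70 of 70 without a low-count filter, 61 of 66 with 1000 UMIs, 53 of 60 at Leiden resolution 2, 32 of 66 with doublets kept, 30 of 67 by DESeq2 and 27 of 60 under 1% mitochondrial. Ago2 stayed between 0.33 and 0.51 in glutamatergic nuclei with each library left out, and 0 miRNA families passed in any alternative. Endothelial nuclei under 1% mitochondrial gave no value. Where counts moved, the cause was not tested.

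By DESeq2 the count was 1 in GABAergic, 1 in OPC, 0 in vascular, 38 in all, 1 in fibroblast, 1 in cluster 4, 13 in cluster 13 and 1 in cluster 15 nuclei, and with other size factors 16 in cluster 13. Without the low-count filter it was 40 in glutamatergic, 37 in GABAergic, 115 in astrocyte, 29 in oligodendrocyte, 51 in OPC, 5 in microglia, 32 in endothelial, 27 in vascular, 4 in all, 87 in granule, 47 in fibroblast, 35 in cluster 4, 107 in cluster 13, 54 in cluster 15 and 1 in cluster 18 nuclei, 21 and 29 in the Slc17a6-detected and the Gad or Slc6a5-detected cluster 15 nuclei, 25 and 16 for the differences from GABAergic nuclei and astrocytes, and 6 gene lists. With doublets kept it was 3 in OPC, 1 in endothelial and 15 in cluster 13 nuclei. At 1000 UMIs it was 1 in cluster 4 and 4 for the difference from astrocytes. At Leiden resolution 2 it was 0 in endothelial and 0 in vascular nuclei and 2 shares. At 0.5 it was 0 shares, but no ependymal class was formed there, so its share was not tested. An estimated correlation and fry gave 0 gene lists each, and the exact permutation test 0 shares. Under 1% mitochondrial it was 1 in glutamatergic, 20 in astrocyte, 9 in OPC, 0 in granule and 1 in cluster 13 nuclei, 14 for the difference from astrocytes and 0 shares. Without 1 cluster it was 1 in GABAergic, 7 in OPC and 0 in granule nuclei, and 0 for the difference from GABAergic nuclei.

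Replicates share only a number: deviations of same-numbered libraries correlated from -0.16 to 0.131. With a replicate block the count was 0 in glutamatergic, 1 in oligodendrocyte, 33 in endothelial, 3 in vascular, 7 in granule, 15 in cluster 4, 161 in cluster 13 and 1 in cluster 15 nuclei and 0 shares, with an ependymal log2 ratio of 3.29 and an adjusted p of 0.0878. With the crossed replicate block it was 1 in glutamatergic, 14 in GABAergic, 169 in astrocyte, 49 in OPC, 17 in microglia, 0 in endothelial, 0 in vascular, 115 in all, 24 in granule, 6 in fibroblast, 23 in cluster 13, 1 in cluster 15 and 1 in cluster 18 nuclei.

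Leaving out each library in turn assumes that the lone library of a group varies like the other group. The lowest and highest counts were 0 and 38 in glutamatergic, 6 and 44 in GABAergic, 26 and 270 in astrocyte, 7 and 129 in oligodendrocyte, 24 and 42 in OPC, 0 and 49 in microglia, 0 and 61 in endothelial, 0 and 96 in vascular, 0 and 364 in all, 0 and 129 in granule, 7 and 55 in fibroblast, 6 and 116 in cluster 4, 42 and 222 in cluster 13, 6 and 168 in cluster 15 and 0 and 48 in cluster 18 nuclei. They were 10 and 46 in the Slc17a6-detected and 8 and 92 in the Gad or Slc6a5-detected cluster 15 nuclei, 0 and 35 for the difference from GABAergic nuclei, 3 and 55 for that from astrocytes, 2 and 7 for gene lists and 0 and 1 for shares.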

Other observations

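The tests of free RNA for Mbp, of hindbrain tissue and of a lower share of another class were chosen only after the result was seen, and the classes described here were added after the data were seen. Fkbp5 was tested in 11 separate classes and passed in 3 of them, with a median log2 change of 1.09. Hif3a, of the hypoxia-inducible factor family, was higher in 8 of 8 classes and passed in 2. Kcnip1, a partner of potassium channels, was higher in 11 of 13 and passed in 2. Mbp, of the myelin sheath, was lower in 12 of 13 and passed in 4, and Fth1, the ferritin heavy chain, was lower in 11 of 12 and passed in 1.

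In cerebellar granule neurons 0 of 9423 genes rose and 1 fell. Mbp went from 503 ± 14 to 201 ± 23.3 CPM (log2 change -1.32, SE 0.14, adjusted p 0.00818), and 0 genes passed without WT replicate 1. The change of Mbp in cerebellar granule neuron nuclei stayed between -1.44 and -1.21 with each library left out. Cluster 27, with Mbp and Fth1 among its 10 leading genes, was 4.64% and 3.65% of granule nuclei in the WT libraries and 0.87% and 0.73% in the cKO libraries. Without that cluster 0 genes passed (Mbp -1.02), and in nuclei under 1% mitochondrial also 0 (Mbp -1.21). At Leiden resolution 2 the granule nuclei of the groups lay in different clusters: its cluster 7 held 305 and 832 WT and 73 and 144 cKO nuclei, and its unnamed cluster 9, led by Grm4, Il16 and Fat2, 101 and 168 WT and 363 and 239 cKO nuclei. The fibroblast growth factor Fgf1 had a change of 1.41, Fth1 of -1.28, the kinase Prkca of 0.92 and the plexin Plxnc1 of 1.45, each with an adjusted p of 0.131. In fibroblasts 0 of 6535 genes passed by edgeR, 380 had an unadjusted p under 0.05 and DESeq2 called 1. Rgs7bp had a change of 1.38, the collagens Col25a1, Col4a6 and Col8a1 of 1.60, -1.12 and 2.49, and Samd5 of -1.57. In the unnamed cluster 4, 0 of 6522 genes passed by edgeR, 403 had an unadjusted p under 0.05 and DESeq2 called 1, with the adhesion gene Kirrel3 at 0.83 (adjusted p 0.0564), Tmem163 at 1.23, Fth1 at -1.55, Tmsb4x at -1.79 and Rgs5 at -3.23. Leaving out single libraries gave 0 to 129 genes in granule neurons, 7 to 55 in fibroblasts and 6 to 116 in cluster 4.

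Slc17a6, the driver gene, had 125 CPM in cluster 18, 71.9 in cluster 15, 70.7 in the unnamed cluster 23 and 62.5 in cluster 4. Cluster 15 was mixed, with Slc17a6 detected in 28.2% of its nuclei and Gad2 in 34.7%. Ago2 had a log2 change of -0.30 (SE 0.47) in cluster 18, 0.05 (SE 0.16) in cluster 15, 0.00 in its nuclei with Slc17a6 detected and -0.21 (SE 0.25) in cluster 4, and passed in none of them. In the nuclei with Slc17a6 detected it was -0.391 without cKO replicate 2 and 0.322 without cKO replicate 1. In cluster 15, 0 of 12504 genes passed by edgeR, 526 had an unadjusted p under 0.05 and DESeq2 called 1. The vasopressin gene Avp had 1.16 ± 0.06 CPM in WT and 29.9 ± 21.4 in cKO (log2 change 4.65, SE 0.66, adjusted p 0.371), Stac a change of 0.91, Peak1 of -0.71, Mbp of -1.29 and Rab11fip1 of 2.77. In cluster 18, 0 of 3203 genes passed by edgeR, 99 had an unadjusted p under 0.05 and DESeq2 called 0, with the neuropeptide S receptor Npsr1 at -3.18, Mbp at -1.70 and Tcerg1l at 1.71. Among cluster 15 nuclei with Slc17a6 detected, 0 of 8350 genes passed by edgeR, 317 had an unadjusted p under 0.05 and DESeq2 called 0, with Mbp at -1.30, Stac at 1.40, Tmem132d at -0.80, Aifm3 at -1.15 and Snapc5 at -2.58. Among those with Gad1, Gad2 or Slc6a5 detected, 0 of 9399 passed by edgeR, 358 had an unadjusted p under 0.05 and DESeq2 called 0, with Mbp at -1.16, Malat1 at -0.47 and Prdm16 at 1.07. None of 12 miRNA families passed in cluster 15, cluster 18 or the nuclei with Slc17a6, with smallest adjusted p of 0.974, 0.979 and 0.998, and 0 had an unadjusted p under 0.05. Leaving out single libraries gave 6 to 168 genes in cluster 15, 0 to 48 in cluster 18, and 10 to 46 and 8 to 92 in the parts of cluster 15.

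Cluster 13 held nuclei with few UMIs, and 4 of its 6261 genes rose and 4 fell. Thsd7b, Reln, Ndnf and the elastin gene Eln had changes of 1.78, 2.31, 2.67 and 2.77, and the Purkinje cell genes Pcp2 and Pcp4, the chaperone Hspa8 and Uqcr11 of -3.32, -1.84, -1.70 and -1.96. Pcp2 had 83 and 97 UMIs in the WT and 11 and 0 in the cKO libraries, and its change ranged from -9.193 to -2.621 with a library left out. At Leiden resolution 2 these nuclei lay mainly in its cluster 15, led by Pcp2, with 117 and 120 WT and 68 and 11 cKO nuclei, and its cluster 16, with Reln among the leading genes and 223 and 185 WT and 141 and 132 cKO nuclei. A changed mix of these parts was not separated from changes within them. In nuclei under 1% mitochondrial 1 gene passed and 0 of these 8 did, and leaving out single libraries gave 42 to 222 genes.

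Mitochondrially encoded genes had a negative median in each class tested, from -0.22 in fibroblasts to -1.32 in OPC, with 6 past the threshold in OPC and 0 elsewhere. Stress genes had medians from -0.44 in cluster 13 to 0.20 in fibroblasts, with 1 past the threshold, Hspa8 in cluster 13. Sex-linked genes had 0 past the threshold in each class. In glutamatergic nuclei the regional lists had 0 members past the threshold, with medians of 0.10 for thalamic, 0.07 for hippocampal granule, 0.22 for cerebellar granule, -0.06 for upper-layer and -0.02 for deep-layer genes. In astrocytes 7 of 8 thalamic genes were positive and 1 passed, Zfhx3.

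Mbp was lower in cKO in 12 separate classes other than oligodendrocytes. Lower expression within oligodendrocyte nuclei is argued against, because the log2 change there was 0.003 (SE 0.17) against a median of -1.33 over the classes. That value does not bear on the number of oligodendrocytes. Their share was 6.10% and 6.20% in WT and 3.88% and 4.77% in cKO (log2 ratio -0.51, SE 0.18, edgeR adjusted p 0.235), and its part in the Mbp change was not tested. Less free RNA in the libraries labelled cKO may contribute: the genes leading the low-UMI cluster had a median change below 0 in 12 of 12 classes (100%), though in cluster 18 just 2 of them were tested, 1 lower and 1 higher. These genes were chosen from the same 4 libraries, in a cluster of 364 and 307 WT and 225 and 141 cKO nuclei. The choice may thus favour genes high in WT, and the classes, which share the libraries, are not independent. How the nuclei were prepared is not known per library, and an effect of genotype stays open.

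Ependymal and cluster 15 nuclei had higher shares in both cKO libraries, and for cluster 15 the test did not pass. A lower share of another class is argued against, since it would raise the other classes alike, and the log2 ratios lay 3.312 (SE 0.41) and 0.69 (SE 0.16) above the median of the other classes. More hindbrain tissue in cKO cannot be told apart, because granule nuclei had a log2 ratio of -0.14 (SE 0.22); the cluster 15 ratio was 0.776 (SE 0.27) higher, which goes against equal gains in both but not against unequal sampling of hindbrain parts. Removal of WT ependymal nuclei by the mitochondrial maximum cannot be told apart either: 44 of 50 marker-positive WT barcodes and 49 of 70 in cKO were removed, and with them put back the log2 ratio was 0.955 (SE 0.65) against 2.32 for the nuclei kept. An effect of genotype on these cells stays open as well.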
